A study of Homo sapiens with 12 samples.

How the data were processed

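Per the labels, RNA was extracted with TRIzol and made into directional libraries of mRNA selected by oligo-dT. The processing notes of the submitters name STAR 2.7, featureCounts 1.6.3 from Subread, DESeq2 1.22.1 and the human genome build hg19. The gene annotation, the strand setting, the treatment of reads with several matches and the design formula are not given. Genes are named by the symbols in the tables, and no coordinates are given, because the annotation at hand is for another build.

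The authors deposited 3 tables of 26364 genes, for DSI P3 against NT P3, DSI P6 against NT P6 and NT P6 against NT P3. The values per library and their mean are a signal in the deposited tables: reads per gene divided by a DESeq2 size factor for each library, estimated separately in each table, and called normalized counts here. The deposited tables also give, per the file headers, the log2 fold change with its standard error, the Wald statistic (a score) and the p-value with its adjusted value. Every positive value was a whole multiple of its library's smallest step within 0.01, so whole reads were recovered by dividing by that step. The reads of NT P3 replicate 3 came from the table of the NT passages, because its size factor in the other table was too near 1 to tell a step from rounding. Levels were compared only within a table, because size factors differ between tables. The comparison of DSI P6 with DSI P3, chosen after the data were seen, has no deposited table. It used recovered reads scaled with DESeq2 size factors.

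XIST, TSIX and Y-linked genes (108) and 7 genes whose presence varies between people were left out, and 26249 genes were kept. Each comparison used genes with at least 10 normalized counts in at least 3 libraries. Log2 of the normalized count plus 1 was tested with limma 3.58.1 (empirical Bayes with a trend on mean expression, two-sided), and p-values were adjusted by the method of Benjamini and Hochberg within a comparison, with a threshold of 0.05. The labels give no pairing of replicates, so no block was used. The interaction test asked whether the difference between DSI and NT cells changed from P3 to P6, in a fit of all 12 libraries with each passage from its own table. A gene with 0 reads in a group is given a bound from 3 reads over the 3 libraries of that group in place of 0, and a gene with 1 to 3 reads a ratio with a 95% exact counting interval. Intervals and bounds cover counting error only, and the labels mention no molecular identifiers. Fitted log2 fold changes of genes with few reads in a group are pulled toward 0 by the added count of 1.

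The tests, the named-gene rule and 33 gene lists were fixed before the data were examined. The named genes of each comparison of groups were the 10 largest rises and 10 largest falls in log2 fold change among genes past the threshold, without overlap between groups and with a mean of at least 100 in the higher group. Clones, pseudogenes and similar names were left out. Some genes that these rules select are not reported here, though the tests and gene counts include them. Up to 4 members were named per list, from the largest changes among members past the threshold with a mean of at least 10, and the interaction named 5 genes in each direction. SMAD7, ID1, ID3, AXIN2, LEF1, LGR5, MKI67, CDKN1A, CDKN2A, TP63, KRT5, KRT14, CDH1, VIM, CFTR, PAX2 and WFDC2 were to be given whatever their values, but LGR5, TP63 and KRT14 did not reach the minimum count in any comparison. The lists covered targets of TGF-β, BMP, WNT, SRF and YAP. Others were epithelial junctions, simple keratins, basal cells, mesenchymal genes, matrix, epididymal epithelium, ion transport, clear cells, secretory genes and squamous genes. Further lists covered G2 and M phases, DNA replication, p53 targets, senescence, inflammation, interferon, cholesterol, glycolysis and hypoxia, the unfolded protein response, steroid response, mitochondrial mRNA, ribosomal proteins and immediate-early genes. Markers of fibroblasts, smooth muscle, endothelium, leukocytes and germ cells stood for other cells. Lists share genes, as CXCL8 (inflammatory, senescence) and CTGF (TGF-β, YAP), and are not independent. Lists with at least 5 measured members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with a correlation estimated per list; list p-values are camera unless fry is named. Counts are of measured members; those over the list alone are past the threshold when p-values are adjusted over that list only. The test ranks a list against all other genes, so its sign can differ from that of the median.

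The alternatives were TMM and upper-quartile scaling, pseudocounts of 0.5 and 5, no filter and a minimum of 50, DESeq2 1.42.0 and edgeR 4.0.16 on recovered reads, the deposited statistics, array weights, a replicate block, a fold threshold, fry for lists, and leaving out each library in turn. On simulated counts with 3 libraries per group, limma recovered 53.7%, 65.7%, 71.6%, 52.2% and 34.3% of planted 1.5-fold changes, and 83.6%, 82.1%, 86.6%, 80.6% and 53.7% of planted 2-fold changes, in the order DSI P3, DSI P6, NT passage, DSI passage and interaction. False calls made up 8.14%, 7.34%, 6.04%, 6.71% and 6.25% of calls in that order, above the nominal 5%. Calculations used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.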

Results

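Expression was measured by RNA sequencing in epithelial cells cultured from the head (caput) of the human epididymis, the duct in which sperm mature. Cells were grown either in standard medium (non treated, NT) or in the same medium with a cocktail of small molecules (called dual SMAD inhibited, DSI), and were collected at passage 3 (P3) or passage 6 (P6). The cocktail held A-8301, DMH-1 and CHIR99021 (1 µM each) and Y27632 (5 µM). The first 3 are known to inhibit, in that order, TGF-β and BMP type I receptors and glycogen synthase kinase 3. The 4 were given only together, so effects cannot be separated. The 12 libraries formed 4 groups of 3 replicates: NT P3, DSI P3, NT P6 and DSI P6. Reads assigned to genes ranged from 14259529 to 21435643 per library: 16891419, 15978224 and 17618284 in NT P3, 16069978, 21435643 and 17956893 in DSI P3, 17705183, 14271666 and 14259529 in NT P6, and 16395318, 15899427 and 17302331 in DSI P6. The 10 most abundant genes took 5.24% ± 0.0189 of reads in NT P3, 6.16% ± 0.173 in DSI P3, 8.72% ± 0.108 in NT P6 and 6.99% ± 0.117 in DSI P6 (SD, n = 3). EEF1A1, a translation elongation factor gene, was the most abundant in 9 libraries. FN1 (fibronectin) led the 3 NT P6 libraries with 3.16% to 3.27% of reads. In DSI P3, replicate 1 stood apart from replicates 2 and 3: chi-square per gene between recovered read counts was 24.4 and 24.4 against these libraries, and 3.63 to 10.1 for every other pair of replicates. The labels do not say whether replicates were separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

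To ask what the cocktail changed in early cultures, DSI P3 was compared with NT P3: 17 of 30 TGF-β target genes fell and 3 rose in the treated cells, 7 of 15 BMP target genes fell, and 13 of 20 secretory genes rose. Of the 21 list calls of this comparison, 0 held with an estimated correlation (adjusted p = 0.0963, 0.189 and 0.0963 for these 3). PMEPA1, which encodes a feedback inhibitor of SMAD signalling, averaged 4384 ± 110.4 normalized counts in NT P3 and 225 ± 56.7 in DSI P3 (SD, n = 3 each), 19.8-fold lower, and the cytokine gene IL11 went from 536 ± 117 to 3.67 ± 3.25. In the other direction, LTF, which encodes the antimicrobial protein lactoferrin, was 378 ± 65.9 in NT P3 and 4200.1 ± 1992 in DSI P3, and PIGR, the receptor that carries immunoglobulin across epithelia, was 512 ± 52.6 and 3542 ± 858. Of 14493 genes tested, 4167 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 1997 up and 2170 down, and 958 of them by at least 2-fold. The 3 values of one group lay wholly above or below those of the other for 45.8% of tested genes, where chance gives 10%. Without NT P3 replicate 1, 2 or 3 the number of changed genes was 2663, 2691 or 2633, and without DSI P3 replicate 1 it was 5086.

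The genes that rose most were DNER, a Notch-related transmembrane gene (log2 fold change 3.93 ± 0.177 SE, adjusted p = 1.09e-06), and PCSK1, which encodes a prohormone convertase (3.84 ± 0.168, adjusted p = 1.09e-06). They were followed by the MHC class II gene HLA-DRA at 3.39 ± 0.226, LTF at 3.38 ± 0.262, the haptoglobin gene HP at 3.33 ± 0.374, SMTNL2, a smoothelin-like gene, at 3.32 ± 0.246, and SLC6A20, an imino acid transporter, at 3.12 ± 0.268. PIGR rose by 2.76 ± 0.148, IL4I1, which encodes an L-amino acid oxidase, by 2.61 ± 0.329, and the endothelin gene EDN2 by 2.58 ± 0.284, with adjusted p from 3.02e-06 to 3.99e-04 over these 3 genes. Log2 fold changes of the strongest falls were -7.03 ± 0.433 for IL11, -4.47 ± 0.307 for the BMP antagonist gene GREM1, -4.31 ± 0.154 for PMEPA1 and -3.87 ± 0.367 for the hair keratin gene KRT81. The LIM-domain gene CRIP1 (-3.86 ± 0.271), the collagen genes COL1A1 (-3.60 ± 0.162) and COL16A1 (-3.44 ± 0.267), the cytoglobin gene CYGB (-3.42 ± 0.258) and TAGLN, which encodes the actin-binding protein transgelin (-3.25 ± 0.159), completed the list of falls. Adjusted p over these 9 genes ran from 4.44e-07 to 7.17e-05.

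Of 30 TGF-β and activin target genes, 17 fell and 3 rose (19 and 3 over the list alone), led by IL11, PMEPA1 and the activin subunit gene INHBA (-3.92). The TGF-β target list median was -0.90 (camera adjusted p = 4.78e-08, or 0.0963 with an estimated correlation). SMAD7, which encodes an inhibitory SMAD, was at -2.85 ± 0.288. Of 15 BMP target genes, 7 fell and 0 rose (8 and 0 over the list alone), with ID3 at -2.66 ± 0.346, ID1 at -2.13 ± 0.237 and TMEM100 at -2.005. The BMP target list median was -0.72 (adjusted p = 0.00171, or 0.189 with an estimated correlation). Of 18 WNT target genes, 8 fell and 1 rose (9 and 3 over the list alone), with the receptor gene EPHB2 at -2.82, the transcription factor gene TBX3 at 2.22 and NKD2, a WNT antagonist gene, at -2.12. The WNT target list median was -0.33 (adjusted p = 0.0170, or 0.183 with an estimated correlation), or -0.19 without NT P3 replicate 1 and -0.20 without NT P3 replicate 2. AXIN2 and LEF1, feedback and effector genes of the WNT pathway, had log2 fold changes of -0.08 ± 0.190 (adjusted p = 0.781) and 0.19 ± 0.140 (adjusted p = 0.342). Of 18 SRF-dependent cytoskeletal genes, 9 fell and 1 rose (as over the list alone), among them TAGLN and the myosin light chain gene MYL9 (-1.65). The SRF list median was -0.41 (adjusted p = 7.76e-05, or 0.198 with an estimated correlation). Of 20 YAP target genes, 13 fell and 1 rose (14 and 2 over the list alone), with ANKRD1 at -2.41 and CTGF at -1.34. The YAP target list median was -0.60 (adjusted p = 2.01e-05, or 0.189 with an estimated correlation).

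Of 28 collagen and matrix genes, 15 fell and 2 rose (as over the list alone), with COL1A1 and the matrix glycoprotein gene THBS1 (-1.94) among the falls. The matrix list median was -0.31 (camera adjusted p = 7.76e-05, or 0.0963 with an estimated correlation). Of 17 mesenchymal genes, 9 fell and 2 rose (as over the list alone), with GREM1 and the transcription factor gene SNAI2 (-1.21) among the falls. The mesenchymal list median was -0.40 (adjusted p = 0.0107, or 0.189 with an estimated correlation). Of 10 fibroblast marker genes, 5 fell and 0 rose (as over the list alone), with the microfibril gene MFAP5 at -1.54. The fibroblast list median was -0.73 (adjusted p = 0.00171, or 0.189 with an estimated correlation). VIM, which encodes the intermediate filament protein vimentin, was at -0.24 ± 0.0694 (adjusted p = 0.0282). The VIM call was lost without DSI P3 replicate 2 (-0.24) or NT P3 replicate 1, 2 or 3 (-0.23, -0.23 and -0.26). Of 6 simple-epithelium keratin genes, 5 fell and 0 rose (6 and 0 over the list alone), with KRT18 at -1.32 and KRT8 at -1.01. The simple keratin list median was -0.85 (adjusted p = 3.62e-04, or 0.189 with an estimated correlation). Of 19 basal-cell genes, 9 fell and 0 rose (9 and 1 over the list alone), with the keratin gene KRT6A at -1.37. The basal-cell list median was -0.21 (adjusted p = 0.0125, or 0.237 with an estimated correlation). The basal keratin gene KRT5 had 0.27 ± 0.101 (adjusted p = 0.0691), past the threshold without DSI P3 replicate 1 (0.31). Of 35 epithelial junction genes, 8 fell and 6 rose (as over the list alone), and the median and the mean (-0.02) differed in sign. The junction list median was 0.05 (adjusted p = 0.991, or 0.994 with an estimated correlation). CDH1, the E-cadherin gene, averaged 4201 ± 62.1 in NT P3 and 4411 ± 847 in DSI P3 (log2 fold change 0.05 ± 0.111, adjusted p = 0.756), a difference within the spread between replicates.

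Of 20 secretory and antimicrobial genes, 13 rose and 0 fell (16 and 0 over the list alone), led by LTF, PIGR, the adhesion gene CEACAM1 (2.41) and VTCN1 (2.22), a B7-family gene. The secretory list median was 1.11 (camera adjusted p = 1.40e-09, or 0.0963 with an estimated correlation). Of 22 epididymal epithelium genes, 10 rose and 0 fell (11 and 1 over the list alone), with the clusterin gene CLU at 1.56, the defensin gene DEFB1 at 0.86 and WFDC2, which encodes the secreted protein HE4, at 1.25 ± 0.145. The epididymal list median was 0.27 (adjusted p = 0.00271, or 0.116 with an estimated correlation). Of 21 ion and water transport genes, 10 rose and 2 fell (11 and 2 over the list alone), with the aquaporin genes AQP3 at 2.06 and AQP1 at 1.84. The transport list median was 0.43 (adjusted p = 3.61e-04, or 0.0963 with an estimated correlation). CFTR, a chloride channel gene, was at 0.36 ± 0.0947 (adjusted p = 0.0178) and PAX2, a transcription factor gene of the duct, at 0.10 ± 0.0864 (adjusted p = 0.441). The CFTR call was lost without NT P3 replicate 2 or 3 (0.36 and 0.34). Of 10 squamous genes, 4 rose and 0 fell (as over the list alone), with the kallikrein genes KLK5 at 1.21 and KLK7 at 1.20. The squamous list median was 0.49 (adjusted p = 0.0474, or 0.238 with an estimated correlation), or 0.74 without DSI P3 replicate 3, 0.84 without NT P3 replicate 2 and 0.31 without NT P3 replicate 3. The squamous call was lost without DSI P3 replicate 2 (adjusted p = 0.0526). Of 26 interferon-stimulated genes, 11 rose and 1 fell (as over the list alone), with IFIT2 at 1.10 and IRF9 at 1.09. The interferon list median was 0.51 (adjusted p = 0.00687, or 0.217 with an estimated correlation).

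Of 32 genes of the G2 and M phases, 32 fell and 0 rose (as over the list alone), with the cytokinesis gene ANLN at -1.60 and the proliferation marker gene MKI67 at -1.17 ± 0.246. The G2 and M list median was -1.25 (camera adjusted p = 2.65e-12, or 0.268 with an estimated correlation). Of 41 S-phase and DNA replication genes, 35 fell and 0 rose (40 and 0 over the list alone), with UHRF1 at -1.82 and CLSPN at -1.80. The replication list median was -1.14 (adjusted p = 1.12e-11, or 0.310 with an estimated correlation), a call lost in fry (adjusted p = 0.0656). These lists moved with the library that stood apart: G2 and M genes had a median difference from the NT P3 mean of -2.10 in DSI P3 replicate 1, -0.795 in replicate 2 and -0.87 in replicate 3. Without replicate 1, 32 of 32 G2 and M genes (median -0.82) and 40 of 41 replication genes (median -0.70) fell. The kinase inhibitor gene CDKN1A had -0.28 ± 0.0905 (adjusted p = 0.0401). The CDKN1A call was lost without DSI P3 replicate 3 (-0.32) or NT P3 replicate 1 or 3 (-0.24 and -0.25). CDKN2A, which encodes the cell-cycle inhibitor p16, had -0.68 ± 0.245 (adjusted p = 0.0618), past the threshold without DSI P3 replicate 2 (-0.90) or NT P3 replicate 1 (-0.89). Of 29 senescence-associated genes, 13 fell and 3 rose (14 and 5 over the list alone), with the growth factor binding gene IGFBP5 (-2.83) and the growth factor gene AREG (-1.82) among the falls. The senescence list median was -0.28 (adjusted p = 0.00105, or 0.116 with an estimated correlation). Of 17 androgen- and glucocorticoid-responsive genes, 11 fell and 1 rose (12 and 2 over the list alone), with CRISPLD2 at -2.69 and the phosphatase gene DUSP1 at -1.47. The steroid-responsive list median was -0.56 (adjusted p = 3.69e-05, or 0.137 with an estimated correlation). Of 48 ribosomal protein genes, 33 rose and 0 fell (41 and 0 over the list alone), with RPS16 at 0.46. The ribosomal protein list median was 0.22 (adjusted p = 1.20e-11, or 0.237 with an estimated correlation).

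Of 22 immediate-early and heat-shock genes, 8 fell and 4 rose (10 and 4 over the list alone), with FOSB at -2.23. The immediate-early list median was -0.20 (camera adjusted p = 0.0299, or 0.237 with an estimated correlation), or -0.32 without DSI P3 replicate 2. The immediate-early call was lost without DSI P3 replicate 1 (adjusted p = 0.0589) or NT P3 replicate 2 (adjusted p = 0.0501). The lists that did not pass were p53 targets (5 rose and 9 fell of 28, adjusted p = 0.106), NF-κB and inflammatory genes (7 rose and 5 fell of 25, adjusted p = 0.707, median -0.01 and mean 0.01) and cholesterol synthesis (3 rose and 0 fell of 24, adjusted p = 0.854). Nor did glycolysis and hypoxia (3 rose and 5 fell of 27, adjusted p = 0.300), the unfolded protein response with ATF4 targets (6 rose and 2 fell of 23, adjusted p = 0.140) and smooth muscle markers (1 rose and 1 fell of 7, adjusted p = 0.329) pass. Without DSI P3 replicate 1 the cholesterol list passed upward (adjusted p = 0.0336), and without replicate 3 the unfolded protein response (adjusted p = 0.0416) and glycolysis lists (adjusted p = 0.0210) passed. With an estimated correlation these had adjusted p = 0.237, 0.315 and 0.6001. Too few members for a group test were measured for clear cells (1 of 2 rose), endothelium (1 of 3 fell), leukocytes (2 of 4 rose and 1 fell) and germ cells (1 of 4 rose and 1 fell). Of the mitochondrially encoded mRNA list, 0 members were measured.

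The passage comparison in untreated cells, NT P6 against NT P3, gave higher levels of TGF-β targets (26 of 30 rose) and matrix genes (20 of 26 rose). Passage cannot be told apart here from any unrecorded difference between the P3 and P6 cultures, such as batch. Inflammatory genes were also higher in NT P6 than in NT P3 (21 of 25 rose, adjusted p = 0.0507 with an estimated correlation), and G2 and M genes lower (32 of 32 fell). ITGA11, which encodes a collagen-binding integrin subunit, rose from 10.5 ± 5.85 to 3018 ± 199 normalized counts (SD, n = 3 each). MKI67 fell from 5689 ± 328 to 919 ± 78.1, while CDKN2A rose from 162 ± 37.7 to 506 ± 135. LTF fell from 320.0 ± 55.2 to 7.54 ± 3.90, and MUC6, a gel-forming mucin gene, from 4481 ± 150.4 to 89.2 ± 49.3. Of 14304 genes tested, 8605 changed, 4329 up and 4276 down, 2450 of them by at least 2-fold, and the libraries of both groups did not overlap for 64.3%.

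After ITGA11 (log2 fold change 8.16 ± 0.240), the strongest rises were in ADAMTS5, an aggrecanase gene (7.31 ± 0.180), the mesenchymal cadherin gene CDH11 (6.49 ± 0.489), INHBA (5.42 ± 0.209) and NSG1, a neuronal endosome gene (5.35 ± 0.333). SCG2, a secretogranin gene, rose by 5.11, the calsyntenin gene CLSTN2 by 5.05, the carboxypeptidase gene CPA4 by 5.04, ACKR3, an atypical chemokine receptor gene, by 4.80 and the matrix gene EDIL3 by 4.77, with adjusted p over the 10 genes from 1.54e-19 to 2.06e-09. With 0 reads in NT P6, the kallikrein gene KLK7 was at least 231-fold lower and S100A9, which encodes a calprotectin subunit, at least 119.8-fold lower; the bounds set 3 reads over the 3 libraries in place of 0. RARRES1, a retinoid-responsive gene (-5.98 ± 0.335), the glycosyltransferase gene GALNT9 (-5.92 ± 0.379), MUC6 (-5.80 ± 0.234), the membrane channel-like gene TMC5 (-5.46 ± 0.268), LTF (-5.31 ± 0.319), the fibroblast growth factor gene FGF14 (-5.04 ± 0.330) and the kinase gene WNK2 (-4.92 ± 0.598) followed.

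Of 30 TGF-β and activin target genes, 26 rose and 1 fell (as over the list alone), with CTGF at 3.84 and SMAD7 at 2.18 ± 0.110. The TGF-β target list median was 1.71 (camera adjusted p = 1.07e-14, or 0.0373 with an estimated correlation). Of 26 collagen and matrix genes, 20 rose and 1 fell (as over the list alone), with the fibrillin gene FBN1 at 4.12 and COL1A1 at 2.64. The matrix list median was 0.95 (adjusted p = 1.03e-09, or 0.0201 with an estimated correlation). Of 19 mesenchymal genes, 16 rose and 1 fell (as over the list alone), with FN1 at 3.92, the gelatinase gene MMP2 at 3.36 and VIM at 0.63 ± 0.0326. The mesenchymal list median was 1.04 (adjusted p = 1.38e-08, or 0.0507 with an estimated correlation). Fibroblast markers (median 1.25, adjusted p = 4.74e-04, or 0.0507 with an estimated correlation) and p53 targets (median 0.23, adjusted p = 0.0116, or 0.0854) were higher as lists, with BTG2 at 1.601. Of 18 SRF-dependent cytoskeletal genes, 17 rose and 0 fell (as over the list alone), with TAGLN at 3.80 and MYL9 at 3.44. The SRF list median was 1.47 (adjusted p = 1.73e-13, or 0.0765 with an estimated correlation). Of 20 YAP target genes, 15 rose and 2 fell (as over the list alone), with ANKRD1 at 3.32. The YAP target list median was 0.51 (adjusted p = 1.29e-05, or 0.0426 with an estimated correlation). Of 25 NF-κB and inflammatory genes, 21 rose and 1 fell (as over the list alone), with the chemokine genes CCL20 at 4.14 and CXCL8 at 3.54. The inflammatory list median was 1.89 (adjusted p = 8.38e-14, or 0.0507 with an estimated correlation). Of 31 senescence-associated genes, 26 rose and 4 fell (as over the list alone), with the protease gene MMP10 at 5.14 and ANGPTL4, a lipase inhibitor gene, at 4.60. The senescence list median was 1.64 (adjusted p = 7.04e-12, or 0.0426 with an estimated correlation).

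Of 32 genes of the G2 and M phases, 32 fell and 0 rose (as over the list alone), with the mitotic kinesin gene KIF20A at -2.76. The G2 and M list median was -1.94 (camera adjusted p = 2.88e-24, or 0.0176 with an estimated correlation). Of 41 S-phase and DNA replication genes, 39 fell and 0 rose (as over the list alone), with E2F2, a transcription factor gene of S phase, at -3.44. The replication list median was -1.59 (adjusted p = 7.94e-19, or 0.0483 with an estimated correlation). Of 24 cholesterol synthesis genes, 21 fell and 0 rose (as over the list alone), with HMGCS1 at -1.78. The cholesterol list median was -1.16 (adjusted p = 1.73e-13, or 0.0194 with an estimated correlation). Of 19 secretory and antimicrobial genes, 14 fell and 4 rose (as over the list alone), LTF among the falls. The secretory list median was -1.24 (adjusted p = 0.00324, or 0.170 with an estimated correlation). Of 20 epididymal epithelium genes, 12 fell and 4 rose (as over the list alone), with DEFB1 at -3.36, the estrogen receptor gene ESR1 at -2.36 and WFDC2 at -1.63 ± 0.153. The epididymal list median was -0.40 (adjusted p = 0.0130, or 0.0861 with an estimated correlation). Ribosomal protein genes (median -0.30, adjusted p = 3.76e-14, or 0.0861 with an estimated correlation) were lower and immediate-early genes (median 0.41, adjusted p = 0.0256, or 0.170) higher as lists, with ATF3 at 2.73. Of 20 basal-cell genes, 9 rose and 5 fell (as over the list alone), with LAMA3 at 2.81. The basal-cell list median was 0.29 (adjusted p = 0.0431, or 0.130 with an estimated correlation), or 0.14 without NT P6 replicate 3. The basal-cell call was lost without NT P6 replicate 1, 2 or 3 (adjusted p = 0.0649, 0.0509 and 0.0820). Of 24 unfolded protein response and ATF4 target genes, 15 rose and 6 fell (16 and 6 over the list alone). The unfolded protein response list median was 0.49 (adjusted p = 0.0431, or 0.130 with an estimated correlation). The unfolded protein response call was lost without NT P6 replicate 1, 2 or 3 (adjusted p = 0.0590, 0.0593 and 0.0638), without NT P3 replicate 3 (adjusted p = 0.0528) or for genes of at least 50 normalized counts (adjusted p = 0.0858).

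Single genes changed in NT P6 against NT P3 included ID3 (3.02 ± 0.189), ID1 (1.53 ± 0.139), AXIN2 (-0.78 ± 0.131), LEF1 (-0.61 ± 0.160), KRT5 (0.79 ± 0.0770) and PAX2 (-0.40 ± 0.0952), with adjusted p from 3.44e-12 to 0.00236. CDH1 averaged 3559 ± 54.8 in NT P3 and 3557 ± 312 in NT P6 (adjusted p = 0.946), within the spread between replicates. CFTR (-0.21 ± 0.0750, adjusted p = 0.0186) lost its call without NT P6 replicate 2 or 3 (-0.18 and -0.17) or NT P3 replicate 1 (-0.19). CDKN1A (0.17 ± 0.0633, adjusted p = 0.0287) lost it without NT P6 replicate 2 or 3 (0.12 and 0.16) or NT P3 replicate 2 (0.09). Lists with a median and a test of opposite sign, none past the threshold, were WNT targets (median -0.25, camera adjusted p = 0.808), epithelial junction genes (-0.01, 0.715), simple keratins (0.13, 0.808) and smooth muscle markers (-0.37, 0.601). The lists of BMP targets (9 rose and 3 fell of 15, adjusted p = 0.148), ion transport, squamous, interferon-stimulated, glycolysis and hypoxia, and androgen- and glucocorticoid-responsive genes did not pass either (adjusted p = 0.114 to 0.605).

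Between treated and untreated cells at P6, the comparison that asks how late cultures differ with the cocktail, 28 of 30 TGF-β target genes, 18 of 26 matrix genes (7 rose) and 24 of 25 inflammatory genes fell with the cocktail. Among secretory genes 12 of 15 rose and among epididymal genes 12 of 19 (5 fell), list calls lost with an estimated correlation (adjusted p = 0.122 and 0.0809). IL11 averaged 1982 ± 33.9 normalized counts in NT P6 (SD, n = 3) and had 0 reads in DSI P6, at least 2212-fold lower. PIGR went from 31.6 ± 17.9 in NT P6 to 4887 ± 309 in DSI P6, LTF from 7.43 ± 3.85 to 2133 ± 251, and WFDC2 from 159 ± 38.1 to 1069 ± 99.6. HLA-DRA averaged 1827 ± 196 in DSI P6 against 2 reads in all of NT P6, a ratio of 2501 with a 95% counting interval of 692 to 20649. Of 14368 genes tested, 7954 changed, 3890 up and 4064 down, 2483 of them by at least 2-fold, and the groups did not overlap for 61.5%.

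Other strong rises were in HLA-DRB1, also of MHC class II (log2 fold change 8.41 ± 0.451, uncertain because near-identical genes share its reads), LTF (8.07 ± 0.257), PCSK1 (7.48 ± 0.556) and PIGR (7.36 ± 0.244). Genes with 0 reads in NT P6 were at least 154-fold higher for HNF4A, a nuclear receptor gene, 153-fold for NDRG2, a differentiation-associated gene, 152-fold for HP and 120.5-fold for the secretin receptor gene SCTR. C4BPA, a complement regulator gene, had 2 reads in NT P6, a ratio of 288 (95% counting interval 79.7 to 2378). Among the falls were ITGA11 (-9.92 ± 0.468), INHBA (-8.66 ± 0.484), the cytokine gene IL33 (-7.50 ± 0.487) and the microfibril gene MFAP2 (-7.14 ± 0.450). With 0 reads in DSI P6, CRIP1 was at least 502-fold lower, CDH11 at least 233-fold and CNTNAP2, a neurexin-family gene, at least 212-fold. CYP24A1, which encodes the vitamin D hydroxylase, had 2 reads there, a ratio of 359.8 (95% counting interval 99.6 to 2971).

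Of 30 TGF-β and activin target genes, 28 fell and 1 rose (as over the list alone), with PMEPA1 at -5.92 and SMAD7 at -4.82 ± 0.195. The TGF-β target list median was -2.66 (camera adjusted p = 3.43e-17, or 0.0221 with an estimated correlation). Of 15 BMP target genes, 9 fell and 1 rose (as over the list alone), with ID3 at -6.89 ± 0.549 and ID1 at -4.25 ± 0.183. The BMP target list median was -1.53 (adjusted p = 0.00452, or 0.0998 with an estimated correlation). AXIN2 rose by 0.98 ± 0.134 and LEF1 by 1.06 ± 0.151, while the WNT target list did not pass (5 rose and 10 fell of 17, adjusted p = 0.107), with EPHB2 at -6.01. Of 19 SRF-dependent cytoskeletal genes, 17 fell and 0 rose (as over the list alone), with TAGLN at -6.35 and MYL9 at -5.79. The SRF list median was -1.17 (adjusted p = 9.25e-11, or 0.0221 with an estimated correlation). Of 26 collagen and matrix genes, 18 fell and 7 rose (as over the list alone), with COL1A1 at -7.13 but the fibrillar collagen gene COL3A1 at 4.06. The matrix list median was -1.23 (adjusted p = 3.97e-06, or 0.0448 with an estimated correlation). Of 19 mesenchymal genes, 17 fell and 0 rose (as over the list alone), with GREM1 at -6.24, SNAI2 at -3.35 and VIM at -0.65 ± 0.0435. The mesenchymal list median was -1.53 (adjusted p = 1.98e-10, or 0.0221 with an estimated correlation). Lower as lists were also YAP targets (median -0.53, adjusted p = 4.01e-04, or 0.102 with an estimated correlation) and fibroblast markers (median -0.85, or -1.43 without DSI P6 replicate 3, adjusted p = 0.0110, or 0.236), with the tissue factor gene F3 at -2.95. Of 25 NF-κB and inflammatory genes, 24 fell and 1 rose (as over the list alone), with CCL20 at -6.80, the growth factor gene CSF3 at -5.31 and TNF at -3.96. The inflammatory list median was -2.14 (adjusted p = 3.44e-15, or 0.0448 with an estimated correlation). Of 31 senescence-associated genes, 25 fell and 3 rose (as over the list alone), with CSF2 at -5.28 and CXCL8 at -3.74. The senescence list median was -2.13 (adjusted p = 2.49e-12, or 0.0221 with an estimated correlation).

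Of 18 basal-cell genes, 14 fell and 3 rose (as over the list alone), with KRT6A at -3.72, KRT17 at -3.49 and KRT5 at -2.95 ± 0.1. The basal-cell list median was -1.60 (camera adjusted p = 1.13e-04, or 0.0448 with an estimated correlation), or -0.93 without NT P6 replicate 1 and -0.97 without NT P6 replicate 2. Of 6 simple-epithelium keratin genes, 6 fell and 0 rose (as over the list alone), with KRT7 at -1.64. The simple keratin list median was -1.17 (adjusted p = 1.23e-04, or 0.0919 with an estimated correlation). Of 15 secretory and antimicrobial genes, 12 rose and 2 fell (13 and 2 over the list alone), with AGR2, a secretory-pathway gene, at 4.74 and the elafin gene PI3 at -3.90. The secretory list median was 2.02 (adjusted p = 5.23e-07, or 0.122 with an estimated correlation). Of 19 epididymal epithelium genes, 12 rose and 5 fell (as over the list alone), with the prostaglandin synthase gene PTGDS at 3.72, DEFB1 at 3.31, ESR1 at 3.10 and WFDC2 at 2.76 ± 0.150. The epididymal list median was 0.63 (adjusted p = 0.00200, or 0.0809 with an estimated correlation), or 0.99 without NT P6 replicate 2 and 0.96 without NT P6 replicate 3. PAX2 rose by 0.63 ± 0.109, and CFTR had -0.05 ± 0.0871 (adjusted p = 0.681). Of 20 ion and water transport genes, 12 rose and 4 fell (as over the list alone), with AQP1 at 3.46 and the potassium channel gene KCNQ1 at 3.23. The transport list median was 0.70 (adjusted p = 0.0308, or 0.143 with an estimated correlation). The transport call was lost without DSI P6 replicate 1 (adjusted p = 0.0579) or for genes of at least 50 normalized counts (adjusted p = 0.107). Of 48 ribosomal protein genes, 48 rose and 0 fell (as over the list alone), with RPS16 at 1.05. The ribosomal protein list median was 0.57 (adjusted p = 8.23e-21, or 0.112 with an estimated correlation).

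Of 32 genes of the G2 and M phases, 25 fell and 0 rose (26 and 0 over the list alone), with ANLN at -1.31 and CCNA2, the cyclin A2 gene, at -1.25. The G2 and M list median was -0.64 (camera adjusted p = 1.21e-05, or 0.320 with an estimated correlation). MKI67 had -0.24 ± 0.134 (adjusted p = 0.147), past the threshold only without DSI P6 replicate 1 (-0.41). Of 26 glycolysis and hypoxia genes, 18 fell and 2 rose (as over the list alone), with the glucose transporter gene SLC2A1 at -1.92 and LDHA at -1.70. The glycolysis list median was -0.63 (adjusted p = 5.50e-05, or 0.225 with an estimated correlation). The same held for steroid-responsive genes (median -0.75, adjusted p = 5.89e-04, or 0.0853 with an estimated correlation) and immediate-early genes (median -0.60, adjusted p = 0.00406, or 0.214), with CRISPLD2 at -5.73 and DUSP1 at -2.97. Of 24 cholesterol synthesis genes, 10 rose and 1 fell (as over the list alone), with INSIG1 at -2.39. The cholesterol list median was 0.21 (adjusted p = 0.0172, or 0.473 with an estimated correlation), or 0.0353 without DSI P6 replicate 1. The cholesterol call was lost without DSI P6 replicate 1 (adjusted p = 0.0906). CDKN2A had -0.63 ± 0.222 (adjusted p = 0.0261). The CDKN2A call was lost without DSI P6 replicate 1 or 2 (-0.46 and -0.47), without NT P6 replicate 2 (-0.42) or in DESeq2 (adjusted p = 0.207). CDKN1A had -0.10 ± 0.0611 (adjusted p = 0.180), and CDH1 averaged 3504 ± 309 in NT P6 and 3537 ± 178 in DSI P6 (adjusted p = 0.850), within the spread between replicates. Not past the threshold were epithelial junction genes (8 rose and 15 fell of 34, adjusted p = 0.0704), DNA replication (1 rose and 17 fell of 41, adjusted p = 0.0768) and p53 targets (8 rose and 9 fell of 28, adjusted p = 0.594, median -0.09 but mean 0.03). Neither were interferon-stimulated genes (5 rose and 5 fell of 25, adjusted p = 0.902), the unfolded protein response (8 rose and 14 fell of 24, adjusted p = 0.0768) and smooth muscle markers (1 rose and 2 fell of 7, adjusted p = 0.676, median -0.29 but mean 0.19). Leaving out DSI P6 replicate 3 (adjusted p = 0.0435, or 0.154 with an estimated correlation) or NT P6 replicate 1 (adjusted p = 0.0473, or 0.417) brought the junction list past it. So did leaving out DSI P6 replicate 3 for the unfolded protein response (adjusted p = 0.0454), and NT P6 replicate 3 for DNA replication (adjusted p = 0.0329), but not with an estimated correlation (adjusted p = 0.156 and 0.459).

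**Figure D1:**
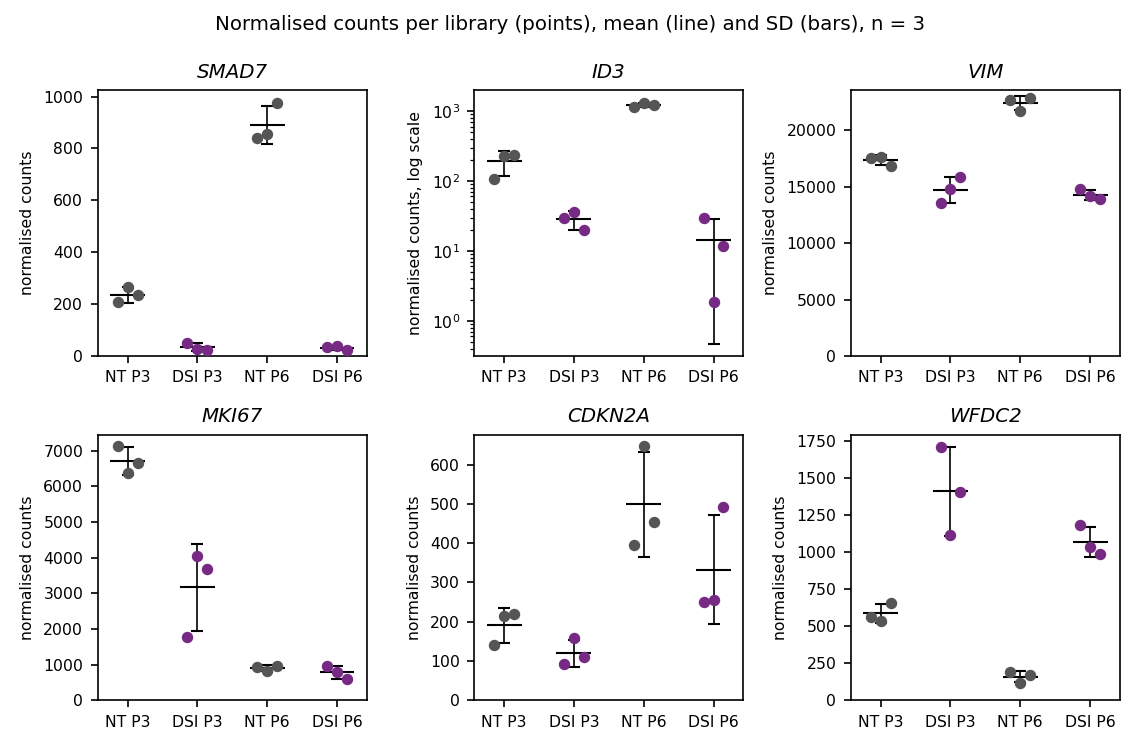
Normalized counts of SMAD7, ID3, VIM, MKI67, CDKN2A and WFDC2 on the vertical axes (log axis for ID3) for each library of the 4 groups on the horizontal axes, with points for libraries, lines for means and bars for the SD (n = 3). P3 and P6 libraries come from separately normalized tables, and ID3 lies at 1228 ± 92.1 in NT P6 and 14.3 ± 13.9 in DSI P6.

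A comparison chosen after the data were seen set DSI P6 against DSI P3, to describe aging in treated cultures. From P3 to P6 in treated cells, 29 of 32 G2 and M genes, 11 of 41 DNA replication genes (1 rose), 19 of 24 cholesterol synthesis genes and 5 of 8 squamous genes fell. Of the 14 list calls of this comparison, 0 held with an estimated correlation (adjusted p = 0.422, 0.540, 0.422 and 0.156 for these 4). FLG, which encodes the epidermal protein filaggrin, rose from 418 ± 41.1 to 8393 ± 332 normalized counts (SD, n = 3 each), and the membrane mucin gene MUC16 from 177 ± 25.3 to 3033 ± 151. KLK7 fell from 713 ± 187 to 14.8 ± 2.20, MKI67 from 3152 ± 1204 to 919.7 ± 227, and CDKN2A rose from 119 ± 34.2 to 392 ± 164. Of 14497 genes tested, 3950 changed, 1945 up and 2005 down, 1043 of them by at least 2-fold, and the groups did not overlap for 42.8%. The number was 2506 without DSI P6 replicate 2, 2621 without DSI P3 replicate 2, 2590 without DSI P3 replicate 3 and 5514 without DSI P3 replicate 1, the library that stood apart.

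FLG (4.33 ± 0.0843), CLSTN2 (4.24 ± 0.527), the protease gene ADAMTS16 (4.18 ± 0.321), MUC16 (4.10 ± 0.114) and the lectin-like gene KLRG2 (3.83 ± 0.448) had the strongest rises on the log2 scale. They were followed by the hair keratin-associated gene KRTAP2-3 (3.66 ± 0.462, uncertain because a near-identical gene shares its reads), the neurotrophin receptor gene NTRK3 (3.58 ± 0.591), RAI2 (3.37 ± 0.354), the alkaline phosphatase gene ALPL (3.29 ± 0.317) and the cyclin D2 gene CCND2 (3.29 ± 0.159). FXYD3, an ion pump regulator gene, had 0 reads in DSI P6 and was at least 191-fold lower. KLK5 (-6.97 ± 0.620), the surface antigen gene PSCA (-6.50 ± 0.547), the adhesion gene CEACAM6 (-6.31 ± 0.638), S100A9 (-6.11 ± 0.661) and KLK7 (-5.47 ± 0.245) also fell. DHRS9, a retinol dehydrogenase gene, was at -5.03 ± 0.390, the interleukin antagonist gene IL1RN at -4.79 ± 0.423, the tissue plasminogen activator gene PLAT at -4.43 ± 0.257 and AQP3 at -4.07 ± 0.358, with adjusted p from 2.06e-06 to 3.04e-05 for these last 4 genes.

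Of 32 genes of the G2 and M phases, 29 fell and 0 rose (31 and 0 over the list alone), with MYBL2, a cell-cycle transcription factor gene, at -2.15 and the mitotic kinase gene PLK1 at -1.97. The G2 and M list median was -1.19 (camera adjusted p = 2.21e-12, or 0.422 with an estimated correlation). Of 41 S-phase and DNA replication genes, 11 fell and 1 rose (as over the list alone). The replication list median was -0.67 (adjusted p = 1.99e-04, or 0.540 with an estimated correlation), or -1.12 without DSI P3 replicate 1, -0.35 without DSI P3 replicate 2 and -0.38 without DSI P3 replicate 3, a call lost in fry (adjusted p = 0.297). Without DSI P3 replicate 1 the G2 and M median was -1.56 with 32 of 32 genes lower, and 38 of 41 DNA replication genes were lower. Of 24 cholesterol synthesis genes, 19 fell and 0 rose (as over the list alone), with INSIG1 at -3.02. The cholesterol list median was -0.82 (adjusted p = 7.13e-09, or 0.422 with an estimated correlation). Of 8 squamous genes, 5 fell and 0 rose (7 and 0 over the list alone), with KLK5 and KLK7 among the falls. The squamous list median was -2.24 (adjusted p = 5.72e-05, or 0.156 with an estimated correlation). Of 28 p53 target genes, 15 rose and 0 fell (17 and 0 over the list alone), with TP53INP1 at 1.23 and ZMAT3 at 1.11. The p53 list median was 0.33 (adjusted p = 1.05e-06, or 0.114 with an estimated correlation).

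Higher as lists were YAP targets (median 0.45, camera adjusted p = 3.68e-04, or 0.374 with an estimated correlation), SRF-dependent genes (median 0.33, adjusted p = 0.00161, or 0.236) and collagen and matrix genes (median 0.42, adjusted p = 0.0206, or 0.236), with ANKRD1 at 3.24 and FBN1 at 2.74. Lower were glycolysis and hypoxia genes (median -0.64, adjusted p = 7.13e-09, or 0.389 with an estimated correlation) and inflammatory genes (median -0.24, or -0.10 without DSI P3 replicate 1, adjusted p = 8.52e-04, or 0.374), with CA9, a carbonic anhydrase gene, at -4.69 and CSF3 at -3.82. So were steroid-responsive genes (median -0.78, adjusted p = 2.96e-05, or 0.156 with an estimated correlation) and simple keratins (median -0.41, or -0.68 without DSI P3 replicate 1 and -0.26 without DSI P3 replicate 3, adjusted p = 0.0206, or 0.389). Of 35 epithelial junction genes, 10 fell and 4 rose (as over the list alone). The junction list median was -0.10 (adjusted p = 0.0414, or 0.440 with an estimated correlation). The junction call was lost without DSI P3 replicate 1 (adjusted p = 0.197), DSI P6 replicate 1 (adjusted p = 0.113) or DSI P6 replicate 2 (adjusted p = 0.0604), or for genes of at least 50 normalized counts (adjusted p = 0.0603). Of 19 secretory and antimicrobial genes, 10 fell and 4 rose (12 and 4 over the list alone), with CEACAM6 and S100A9 lower and MUC16 higher. The secretory list median was -0.63 (adjusted p = 0.0232, or 0.440 with an estimated correlation), or -0.28 without DSI P3 replicate 1 and -0.34 without DSI P3 replicate 3. The secretory call was lost without DSI P3 replicate 1, 2 or 3 (adjusted p = 0.945, 0.120 and 0.286), upward without replicate 1. KRT5 was at -2.45 ± 0.117, CFTR at -0.64 ± 0.108 and CDKN1A at 0.33 ± 0.0810 (adjusted p = 0.0126). The CDKN1A call was lost without DSI P6 replicate 2 (0.30). Log2 fold changes of genes not past the threshold were 0.19 ± 0.388 for SMAD7, -0.62 ± 0.281 for ID1, -1.26 ± 0.751 for ID3, 0.27 ± 0.185 for AXIN2, 0.24 ± 0.137 for LEF1, -0.06 ± 0.116 for CDH1, 0.20 ± 0.0742 for VIM, 0.11 ± 0.107 for PAX2 and -0.14 ± 0.140 for WFDC2, with adjusted p from 0.0679 to 0.752. TGF-β targets (10 rose and 7 fell of 28, adjusted p = 0.418), mesenchymal genes (6 rose and 3 fell of 17, adjusted p = 0.120), epididymal epithelium (4 rose and 5 fell of 21, adjusted p = 0.753) and ribosomal proteins (1 rose and 1 fell of 48, adjusted p = 0.418) did not pass as lists, though mesenchymal genes did at a minimum of 50 normalized counts (adjusted p = 0.0391, or 0.334 with an estimated correlation). Another 10 lists did not pass (adjusted p = 0.0549 to 0.763), 2 of which had a median and a mean of opposite sign, WNT targets (0.00191 and -0.36) and basal-cell genes (0.01 and -0.82). Of these, the fibroblast list passed upward without DSI P3 replicate 2 or 3 (adjusted p = 0.0206 and 0.0241) and the ion transport list downward without DSI P6 replicate 1 (adjusted p = 0.0486), but not with an estimated correlation (adjusted p = 0.409, 0.380 and 0.414).

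**Figure D2:**
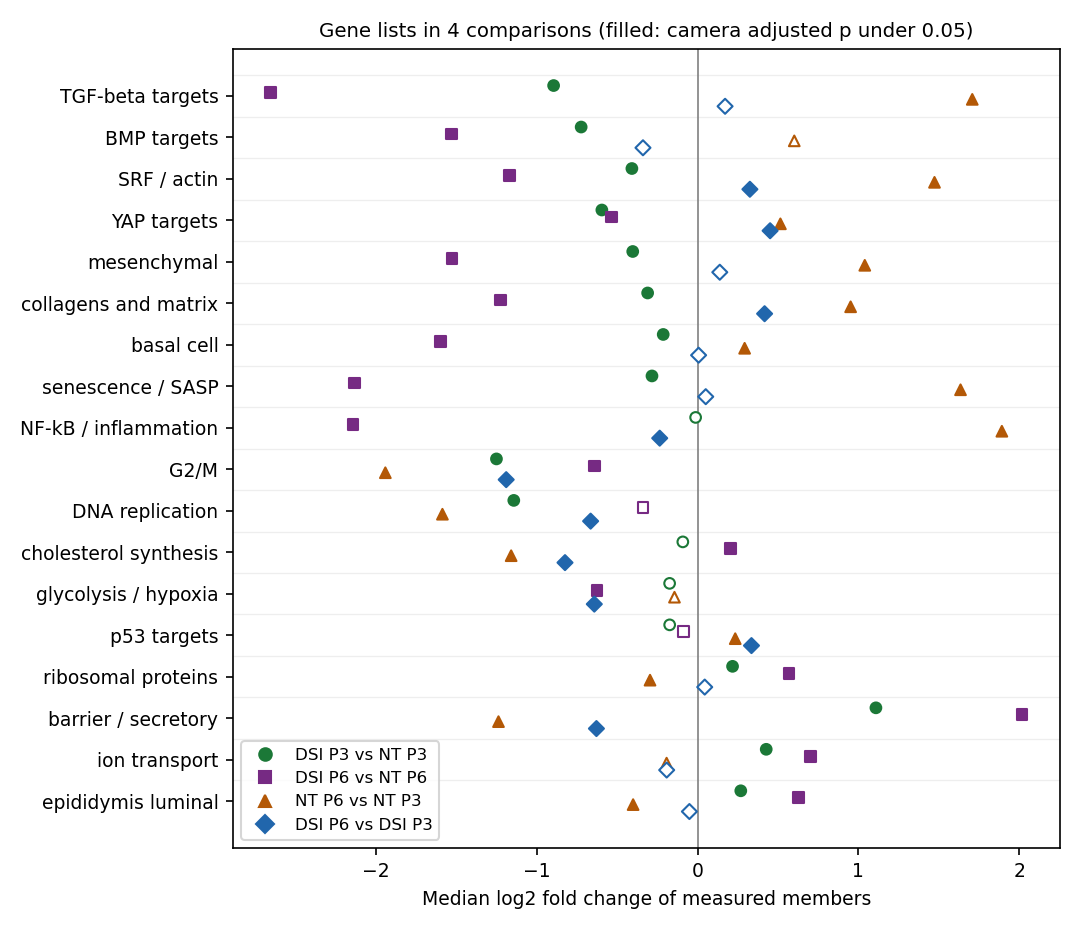
Median log2 fold change of measured members (horizontal axis) for the gene lists (vertical axis) in the 4 comparisons, with a mark for each comparison, filled where the camera adjusted p was under 0.05. TGF-β targets lie at -0.90 for DSI P3 against NT P3, -2.66 for DSI P6 against NT P6, 1.71 for NT P6 against NT P3 and 0.17 for DSI P6 against DSI P3.

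The difference between DSI and NT cells changed with passage for TGF-β target, inflammatory, senescence-associated and epididymal genes. The interaction test took each passage from its own separately normalized table. ID3 had a change of effect from P3 to P6 of -4.23 ± 0.801 on the log2 scale. CCL20, a chemokine gene, averaged 226 ± 36.3 normalized counts in NT P3, 97.3 ± 27.3 in DSI P3, 3349.7 ± 509.6 in NT P6 and 31.7 ± 18.2 in DSI P6 (SD, n = 3 each), a change of the effect of -5.57 ± 0.398. For WFDC2 it was 1.51 ± 0.232 (-1.63 from P3 to P6 in NT and -0.14 in DSI cells). TGF-β target and inflammatory medians also moved further in NT cells, but KRT5 in DSI cells (NT 0.79, DSI -2.45). Of 15132 genes tested, the effect of the cocktail differed between passages for 4293, more positive at P6 for 2095 and more negative for 2198, and by at least 2-fold for 1398.

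The effect became most negative for ITGA11 (-7.28 ± 1.04), CDH11 (-6.35 ± 0.972), ACKR3 (-5.59 ± 0.888), CCL20 and ADAMTS5 (-5.54 ± 0.408). It became most positive for HLA-DRA (6.85 ± 0.516), HLA-DRB1 (5.88 ± 0.580), NDRG2 (5.85 ± 0.451) and HNF4A (5.59 ± 0.554), with adjusted p from 3.01e-08 to 1.46e-04 over the 9 genes. The fitted values of CDH11, ACKR3, NDRG2 and HNF4A rest on groups with 0 reads, and that of HLA-DRA on 2 reads, so they depend on the pseudocount. In edgeR the CDH11 call was lost (adjusted p = 0.9999). For lists, fell and rose mean a more negative and a more positive effect at P6. Of 30 TGF-β and activin target genes, 26 fell and 0 rose (as over the list alone). The TGF-β target list median was -1.78 (camera adjusted p = 2.35e-17, or 0.00129 with an estimated correlation). Of 25 NF-κB and inflammatory genes, 25 fell and 0 rose (as over the list alone). The inflammatory list median was -2.17 (adjusted p = 2.49e-28, or 0.00131 with an estimated correlation). Of 31 senescence-associated genes, 21 fell and 3 rose (22 and 3 over the list alone). The senescence list median was -1.30 (adjusted p = 1.39e-11, or 0.00131 with an estimated correlation). More negative too were the lists of mesenchymal genes (median -1.01, adjusted p = 4.16e-11, or 0.00129 with an estimated correlation) and SRF-dependent genes (median -1.04, adjusted p = 5.63e-12, or 0.00774), with MYL9 at -4.14. The same held for collagen and matrix genes (median -0.63, adjusted p = 2.36e-05, or 0.00544 with an estimated correlation) and basal-cell genes (median -1.04, adjusted p = 3.19e-04, or 0.0428), with COL1A1 at -3.52 and KRT5 at -3.22 ± 0.135.

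Of 22 epididymal epithelium genes, 10 rose and 2 fell (11 and 2 over the list alone), with PTGDS at 3.75. The epididymal list median was 0.45 (camera adjusted p = 0.00378, or 0.0352 with an estimated correlation), or 0.27 without DSI P6 replicate 3. Of 41 S-phase and DNA replication genes, 15 rose and 0 fell (16 and 0 over the list alone). The replication list median was 1.00 (adjusted p = 1.78e-06, or 0.461 with an estimated correlation), or 0.44 without DSI P3 replicate 1. Of 32 genes of the G2 and M phases, 7 rose and 0 fell (2 and 0 over the list alone). The G2 and M list median was 0.65 (adjusted p = 0.00115, or 0.556 with an estimated correlation), or 0.27 without DSI P3 replicate 1. Of 24 cholesterol synthesis genes, 7 rose and 1 fell (as over the list alone). The cholesterol list median was 0.33 (adjusted p = 0.00874, or 0.556 with an estimated correlation), or 0.0681 without DSI P3 replicate 1. Without that library the G2 and M and cholesterol calls were lost (adjusted p = 0.0700 and 0.150), while DNA replication had adjusted p = 1.81e-05. In fry all 3 calls were lost (adjusted p = 0.234, 0.125 and 0.0901 in that order). Of 27 glycolysis and hypoxia genes, 13 fell and 1 rose (14 and 1 over the list alone), with the collagen hydroxylase gene P4HA2 at -2.39. The glycolysis list median was -0.57 (adjusted p = 2.17e-05, or 0.339 with an estimated correlation). The secretory list (median 0.33, adjusted p = 0.00874, or 0.224 with an estimated correlation, LTF at 4.69 and PIGR at 4.59) and the ribosomal protein list (median 0.36, adjusted p = 1.96e-16, or 0.134) were more positive. More negative were the unfolded protein response (median -0.58, adjusted p = 8.93e-04, or 0.128 with an estimated correlation), immediate-early genes (median -0.49, adjusted p = 0.00694, or 0.206) and fibroblast markers (median -0.64, adjusted p = 0.0110, or 0.134).

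AXIN2 (1.06 ± 0.247) and LEF1 (0.87 ± 0.202) had a more positive effect at P6, as did PAX2 (0.53 ± 0.149), and VIM (-0.41 ± 0.0822), SMAD7 (-1.96 ± 0.368) and ID1 (-2.12 ± 0.328) a more negative one. MKI67 had 0.93 ± 0.314 (adjusted p = 0.0349), a call lost without NT P3 replicate 1, 2 or 3 (adjusted p = 0.0791, 0.0561 and 0.0638), NT P6 replicate 1, 2 or 3 (0.0546, 0.0797 and 0.0515) or DSI P6 replicate 1 or 2 (0.101 and 0.0704). It was also lost in DESeq2 (adjusted p = 0.109), with no filter (0.0532) and with the replicate block (0.0521). CFTR had -0.41 ± 0.135 (adjusted p = 0.0322), lost without NT P3 replicate 2 or 3 (adjusted p = 0.0627 and 0.0721), DSI P6 replicate 2 or 3 (0.0802 and 0.0703) or NT P6 replicate 1 (0.0933). CDH1 had -0.04 ± 0.138 (adjusted p = 0.875), CDKN1A 0.18 ± 0.113 (adjusted p = 0.248) and CDKN2A 0.06 ± 0.380 (adjusted p = 0.934). The other 11 lists did not pass (camera adjusted p = 0.0563 to 0.776), and WNT targets (median 0.22, mean -0.41) and smooth muscle markers (median -0.41, mean 0.03) had a median and a mean of opposite sign. The next 19 passes (adjusted p in brackets) were lost with an estimated correlation (adjusted p = 0.114 to 0.502): simple keratins without DSI P3 replicate 1 (0.0112) and junction genes without DSI P3 replicate 2 (0.0279), NT P3 replicate 2 (0.0375) or DSI P6 replicate 3 (0.0265). BMP targets did so without DSI P3 replicate 3 (0.0395), NT P3 replicate 2 (0.0461) or DSI P6 replicate 3 (0.0409). Interferon-stimulated genes passed without DSI P3 replicate 2 (0.0489) or 3 (0.0395) or NT P6 replicate 2 (0.0307) or 3 (0.0108) or with the replicate block (0.0465), and steroid-responsive genes without DSI P3 replicate 1 (0.0338) or NT P3 replicate 1 (0.0418), 2 (0.0350) or 3 (0.0379). At a minimum of 50 normalized counts, junction genes (0.0460), BMP targets (0.0212) and steroid-responsive genes (0.0460) passed too.

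Genes changed by the cocktail tended to change in one direction at both passages: of 3143 genes called at P3 and at P6, 2919 (92.9%) had the same direction. IL11, COL1A1 and TAGLN fell and LTF, PIGR, HLA-DRA and PCSK1 rose at both, and TBX3 was called in opposite directions, at 2.22 at P3 and lower at P6, where 2 reads were left in DSI cells (ratio 47.8, 95% counting interval 13.2 to 394). Both effects rose for 1461 genes, where independent lists would share 533, and fell for 1458, against 602. Across 13958 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r 0.672 and Spearman rho 0.570, and these comparisons share no libraries. The passage effects in NT and in DSI cells, also without shared libraries, gave r 0.543 and rho 0.518, with 88.0% of 3065 genes called in both changing in the same direction.

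Many genes that moved with passage in NT cells had the opposite difference between DSI and NT cells at P6: 4841 of 5670 genes called in both (85.4%), ITGA11, INHBA, CDH11 and LTF among them. Genes higher with the cocktail and lower with passage numbered 2107, against 1097 for independent lists, and the reverse 2734, against 1254. Both comparisons use the NT P6 libraries, where noise or a real change alone makes r negative: r was -0.663 (rho -0.577). Simulated unchanged groups (noise only) gave -0.501, set by sharing a group, so only covariances are compared. The covariance was -0.654, against -0.0290 simulated. The 3 shared libraries cannot be split into sets of at least 2, so covariance and overlap may come from them. The cocktail effect at P3 and the passage effect in NT cells, which share NT P3, gave r -0.0715 and rho 0.0135. The simulated r of 0.502 is set likewise. The covariance was -0.0367 against 0.0315, with the same limit. These correlations have no p-value because genes are not independent.

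**Figure D3:**
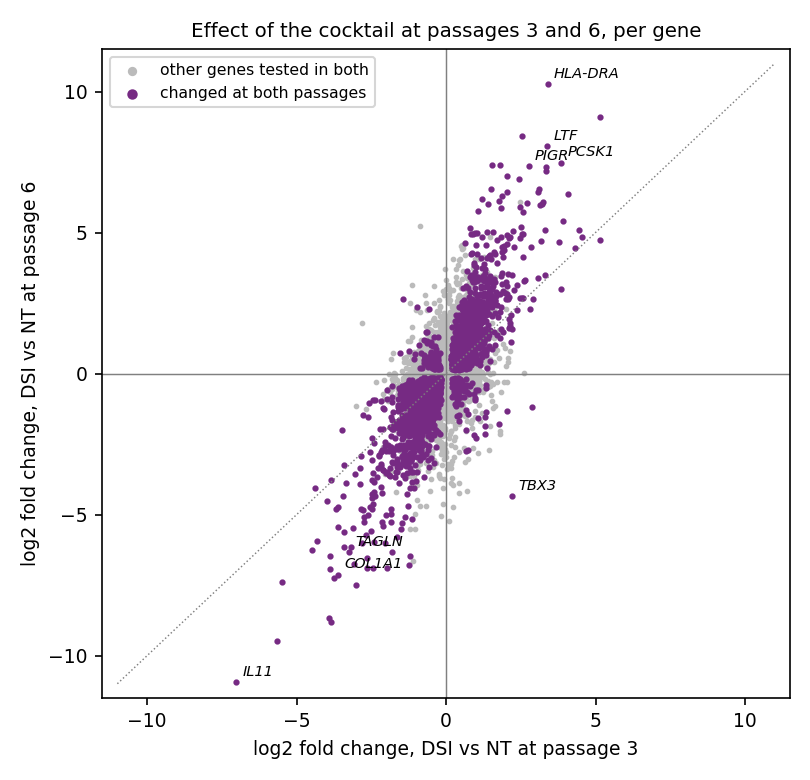
Log2 fold change of DSI over NT cells at passage 3 (horizontal axis) and passage 6 (vertical axis), with a point for each gene tested in both and purple points for genes called at both passages. COL1A1 lies at -3.60 and -7.13, and LTF at 3.38 and 8.07.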

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

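The tests of sequencing depth, of cells of another type, of DSI P3 replicate 1 alone, of lists matched on length and GC content and of both scaling explanations were chosen after the result was seen; the others were set before it. The difference between DSI and NT cells changed from P3 to P6 for 4293 genes by the interaction test itself. Among named genes the log2 change was 6.85 for HLA-DRA, 5.88 for HLA-DRB1, 5.85 for NDRG2, 5.59 for HNF4A, -7.28 for ITGA11, -6.35 for CDH11, -5.59 for ACKR3, -5.57 for CCL20 and -5.54 for ADAMTS5. The median change of the log2 difference was -1.78 for TGF-β targets, -1.04 for SRF-dependent genes, -1.04 for basal-cell genes, -1.01 for mesenchymal genes and -0.63 for matrix genes. It was -1.30 for senescence-associated genes, -2.17 for inflammatory genes, -0.57 for glycolysis and hypoxia, -0.58 for the unfolded protein response, -0.49 for immediate-early genes and -0.64 for fibroblast markers. It was 0.45 for epididymal epithelium genes, 0.33 for secretory genes, 0.65 for G2 and M genes, 1.00 for DNA replication, 0.33 for cholesterol synthesis and 0.36 for ribosomal proteins. Without DSI P3 replicate 1 it was 0.272 for G2 and M, 0.438 for DNA replication and 0.0681 for cholesterol, and without DSI P6 replicate 3, 0.274 for epididymal genes. With an estimated correlation 9 of the 17 list calls were lost (adjusted p = 0.128 to 0.556). These were glycolysis, the unfolded protein response, immediate-early genes, fibroblasts, secretory genes, G2 and M, DNA replication, cholesterol and ribosomal proteins. Of 100 splits of the 12 libraries within passages, the real one included, 7 called as many genes, and the highest other count was 5193, so this count cannot exclude chance. The 6 others as large all kept the P6 groups as labelled, which 10 drawn splits did, and with them the P6 difference itself; limma called 0 genes at most in the 80 splits that kept neither passage's groups. Over all other splits, 105 to 6718 genes had an unadjusted p under 0.05.

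For the comparisons of groups, 1 of 10 splits of the 6 libraries, the real one, gave a count as large in each case, and 10 splits are too few for a share under 0.05. The real count was 4167 for DSI P3, 7954 for DSI P6, and 8605 and 3950 for the NT and DSI passages. The highest other count was 0 in limma in each, with 148 to 307, 56 to 153, 65 to 128 and 82 to 990 genes at an unadjusted p under 0.05 in that order.

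DSI P3 replicate 1 stood apart from replicates 2 and 3, with a median log2 difference of -1.22 for G2 and M genes (0 of 32 higher), -1.38 for DNA replication (0 of 41) and -0.65 for cholesterol synthesis (0 of 24). Sequencing depth as the sole cause is argued against by the other 3 replicate pairs whose depths differed by at least the ratio of 1.12 between replicates 1 and 3: their chi-square per gene was at most 4.92, against 24.4. Cells of another type in place of epithelial cells would lower epithelial junction genes along with the replication genes, but their median difference was -0.0188 (95% bootstrap interval -0.103 to 0.102). An amino acid response in that culture stays open as a candidate explanation: aminoacyl-tRNA synthetase genes had a median difference of 0.4001 (10 of 11 higher), against 0.0555 between replicates 2 and 3 and -0.263 for endoplasmic reticulum chaperones. The design names no difference between replicates of a group, so no biological explanation from it was tested.

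G2 and M genes were lower in DSI P3 than in NT P3, with a median log2 fold change of -1.25, a list call lost with an estimated correlation (adjusted p = 0.268). DSI P3 replicate 1 alone is argued against by a median of -0.816 without it, with 32 of 32 members lower. The list differed by -1.25 from random lists matched on mean expression, of which 95% lay between -0.128 and 0.110. Scaling by a factor per library cancels in this difference, which cannot test it. What stays open is the cocktail itself or any unrecorded difference between the DSI and NT cultures at P3.

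Ribosomal protein genes were higher in DSI P6 than in NT P6, with a median log2 fold change of 0.57 and 48 of 48 members higher, a list call lost with an estimated correlation (adjusted p = 0.112). Gene length and GC content are argued against by 0% of 10000 random lists matched on both with a median as high (their median was 0.0275); removing their trend left 0.553 but decides little, as it explained 0.115% of the variance. Scaling cancels likewise in the difference of 0.928 from lists matched on mean expression. Such lists argue against abundance: 0% of 10000 had a median as high (their median was -0.358). A shared change of mRNAs with a 5′ terminal oligopyrimidine motif (TOP), which mTOR signalling is known to regulate, stays open: other TOP genes had a median of 0.495, with 20 of 20 higher. Reads shared with ribosomal protein pseudogenes were not tested, and the pattern may still be technical.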

How the results depend on the processing

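The alternatives of the DSI passage comparison, the list medians with a library left out, the estimated correlations within other alternatives and the list member counts without DSI P3 replicate 1 were chosen after the result was seen. So were the correlation of passage effects, that of the DSI effect at P6 with the NT passage effect, its simulated controls and, except for the DSI effects at P3 and P6, the limit of 100 in correlations; the other alternatives were set before. The number of changed genes stayed within 1.5 times the reported count under scaling, pseudocount, filter, test, array weights and replicate block. The exception was 6032 genes in the DSI passage comparison with array weights, cause not tested. Requiring at least a 2-fold change left 958, 2483, 2450, 1043 and 1398 genes for DSI P3, DSI P6, the NT passages, the DSI passages and the interaction, by construction. Leaving out 1 library gave 2633 to 5086, 6985 to 7338, 7754 to 8268, 2506 to 5514 and 3670 to 4761 genes in the same order. At least 62.2%, 86.1%, 88.6%, 62.5% and 83.3% of called genes stayed called under each alternative other than the fold threshold, and 0 called in both changed direction.

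Estimated correlations left 0 of 21 list calls for DSI P3, 7 of 20 for DSI P6 and 7 of 18 for the NT passages. They left 0 of 14 for the DSI passages and 8 of 17 for the interaction. Unadjusted, 7, 12, 14, 5 and 9 lists had p under 0.05. In fry, which asks whether a list moved on balance, 22, 26, 26, 19 and 21 lists passed. Leaving out 1 library gave 20 to 23, 18 to 22, 16 to 18, 12 to 14 and 17 to 20 lists. Replicate numbers did not pair the libraries: correlations of same-numbered ones ran from -0.0482 to 0.0349 over 12 pairs. With a replicate block, 3929, 7846, 8860, 3060 and 4103 genes and 21, 20, 18, 14 and 18 lists passed.

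Direction reversed only for values not past the threshold as reported, apart from the secretory list of the DSI passages, and the cause was not tested. With array weights, AXIN2 was at 0.13 and CDH1 at -0.0627 for DSI P3 against NT P3. CDH1 was then at -5.80e-05 for DSI P6 against NT P6, 0.00910 for the NT passages and 0.0509 for the DSI passages, where WFDC2 was at 0.00135. In DESeq2, CDH1 was at 0.000740 for the NT passages. With 1 library left out of DSI P3 against NT P3, AXIN2 ranged from -0.239 (without DSI P3 replicate 2) to 0.171 (without replicate 1), and CDH1 from -0.0988 (without replicate 1) to 0.138 (without replicate 2). The cholesterol list ranged from camera adjusted p = 0.0336, upward, without DSI P3 replicate 1 (adjusted p = 0.237 with an estimated correlation) to 0.897 without NT P3 replicate 3. For DSI P6 against NT P6, CDH1 ranged from -0.0548 (without NT P6 replicate 2) to 0.0720 (without NT P6 replicate 3), with -0.0210 without DSI P6 replicate 3. CFTR ranged from -0.116 (without DSI P6 replicate 1) to 0.0318 (without NT P6 replicate 1). For the NT passages, CDH1 ranged from -0.0594 (without NT P6 replicate 3) to 0.0664 (without NT P6 replicate 2), with 0.00814 without NT P3 replicate 2. For the DSI passages, SMAD7 ranged from -0.0167 (without DSI P3 replicate 3) to 0.527 (without DSI P3 replicate 1), and PAX2 from -0.00640 (without DSI P6 replicate 3) to 0.184 (without DSI P6 replicate 1). CDH1 ranged from -0.148 to 0.0946 and WFDC2 from -0.303 to 0.0126, both lowest without DSI P3 replicate 2 and highest without replicate 1. For the interaction, CDH1 ranged from -0.121 (without DSI P3 replicate 2) to 0.115 (without replicate 1) and CDKN2A from -0.265 (without DSI P6 replicate 3) to 0.277 (without DSI P3 replicate 2), with 0.0640 and -0.132 under array weights. The secretory list of the DSI passages ranged from adjusted p = 0.00839 without DSI P6 replicate 1 to 0.945, upward, without DSI P3 replicate 1.

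Of values of named genes under other alternatives, 1428 of 1456, 1453 of 1460, 1455 of 1469, 1274 of 1294 and 1161 of 1186 kept their direction and their side of the threshold. With 1 library left out these were 698 of 780, 697 of 711, 723 of 744, 662 of 732 and 1336 of 1419. For lists, without the estimated correlation, they were 291 of 300, 280 of 293, 286 of 302, 281 of 299 and 443 of 474. Among genes with a mean of at least 100, the correlation was 0.713 for the DSI effects at P3 and P6 and 0.609 for the passage effects in NT and DSI cells. With the NT passage effect it was -0.660 for the DSI effect at P6 and -0.0310 at P3.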

Other observations

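The gene groups given here were chosen after HLA-DRA, HLA-DRB1 and other values were seen, so their counts are not independent evidence. MHC class II genes, which present antigen, were higher with the cocktail: 8 of 9 measured members rose in DSI P3 against NT P3 (median log2 fold change 1.53), with CIITA, their master regulator, at 1.78 and CD74, the invariant chain, at 1.26. In DSI P6 against NT P6, 10 of 10 rose (median 5.18), and from NT P3 to NT P6, 8 of 8 fell (median -3.05), with CIITA at 6.13 and -4.33. From DSI P3 to DSI P6, 6 of 10 rose and 1 fell (median 0.77), and the effect of the cocktail was more positive at P6 for 9 of 10 (median 3.03). Class II genes include near-identical copies whose reads are uncertain.

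Endoplasmic reticulum chaperone genes, which fold secreted proteins, fell for 12 of 12 members in DSI P6 against NT P6 (median -0.851) and rose for 11 of 12 from NT P3 to NT P6 (median 0.643). In DSI P3 against NT P3, 3 fell and 1 rose (median -0.164), and from DSI P3 to DSI P6, 1 fell and 1 rose (median -0.0463). The effect of the cocktail on them was more negative at P6 for 11 of 12 (median -0.719). Other genes with TOP mRNAs rose for 8 of 20 members in DSI P3 against NT P3 (median 0.136), fell for 16 of 20 with 1 risen from NT P3 to NT P6 (median -0.269), and rose for 3 and fell for 1 from DSI P3 to DSI P6 (median 0.0536). The deposited DESeq2 statistics called 4075 genes for DSI P3, 7584 for DSI P6 and 8123 for the NT passages. Of these, limma also called 3894, 7327 and 7898, all in the same direction.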
